A study of Mus musculus with 4 samples.

How the data were processed

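Cells of C57BL/6J mouse pancreas, depleted of cells carrying CD45, were profiled in 4 single-cell libraries, 1 untreated and 1 each at 1, 7 and 28 days after caerulein. Per the labels, cells of 3 pancreata were mixed for each library, 10000 cells were captured with droplet 3-prime chemistry, and all libraries shared a sequencing lane. The deposited table holds raw UMI counts per gene and cell, which the authors made with Cell Ranger on the mouse genome mm10 according to the submitters' processing notes. The version of Cell Ranger and the filter on cells are not given in the sources used here. The table has 31053 genes, 10194 of them without a UMI, and 33681 columns. Columns of the caerulein libraries carry the day in their names, and those of the untreated library were assigned by elimination.

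The libraries differ in depth. The untreated, day 1, day 7 and day 28 libraries hold 6943, 10550, 8803 and 7385 barcodes with medians of 6871, 38074, 19720 and 8141 UMIs and 1930, 5444, 4211 and 933 genes. No cell in the table has under 201 or over 7993 genes or over 14.9892% mitochondrial UMIs, so a filter was applied before deposit. A filter on genes differed between libraries, as 5491 genes of the untreated library but only 42, 187 and 170 of the caerulein libraries are seen in under 20 cells. Genes absent from a whole caerulein library were therefore treated as removed, are called listed at 0, and were given no ratio. This was decided after first medians had been seen.

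Cells with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5, called 138 doublets in the untreated library (1.99%), which were removed, and 0%, 0.0114% and 0.0406% of cells in the others, which were kept because a call under 0.5% was set to be ignored. The 6805, 10548, 8801 and 7385 cells left were scaled to 10000 UMIs each and log transformed. With 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 they formed 37 clusters. No batch correction was made, since library and time point are the same thing. A cluster was given the class, such as acinar-like, with the highest mean log2 ratio of markers among classes with at least 3 markers seen in at least 25% of its cells. It stayed unnamed if its top 10 genes held markers of other classes and no more of its own, or if it was shallow and they held none of its own. Other clusters could be named with 0 own markers in the top 10, as were the day 1 fibroblast-like clusters 27, 29, 33 and 34. In all, 5 definitions of the fold behind the top 10 genes were looked at, and the one used was taken after the clusters had been seen. A list of 10 intestinal genes, added then too, left 2 clusters unnamed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

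Counts were summed per class and library and scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, giving counts per 1e6 of the scaled total (CPM). A ratio is the scaled CPM of a caerulein library over that of the untreated library, with an exact conditional binomial interval of 95%. With 1 library per time point there is no spread between samples, so no test was run and no p-value is given, and all intervals cover counting error only. Where a library has 0 UMIs of a gene, the ratio is a bound from 3 UMIs. Shares of cells have exact binomial intervals of 95%. Classes with at least 100 cells in every library were compared. Endocrine-like cells met this rule, but their day 1 comparison was left out after it was seen that most of those cells share a barcode with a deeper cell of another library.

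The gene lists, marker lists, scaling, intervals and most alternatives were set before the data were examined. There are 20 lists with 412 genes, covering digestive enzymes, acinar identity, ductal and metaplasia genes, the gastric lineage, immediate early genes, MAPK output, inflammatory mediators, acute phase and Reg genes, the unfolded protein response, S phase, G2/M, interferon and antigen presentation, oxidative stress, lysosome and autophagy, heat shock, oxidative phosphorylation, ribosome biogenesis, amino acid metabolism, matrix genes and endothelial activation. The value of a list is the median log2 ratio of its members with at least 10 UMIs over both libraries. Its percentile is that among 10000 random lists of the same size matched on mean expression in 20 bins, and members count as higher or lower from 2-fold with an interval that excludes 1.

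Named genes follow a rule of size. In acinar-like cells these are the 8 highest and 8 lowest per day by the ratio of CPM plus 5, and in other classes the 5 highest and 5 lowest. They needed 50 CPM in the higher library and at least 10% of the level in the other class, of at least 50 cells, where the gene is highest. Mitochondrial, ribosomal protein, haemoglobin and sex-linked control genes were left out. Up to 4 members per list with at least 10 CPM were named too, and some genes that these rules selected are not reported here. For the genes followed over time, the 50 highest and the 50 lowest at day 1 were taken by the same ratio, with the eligibility of the named genes, which the plan had left open. Shares of cells with a G2/M UMI were taken after each cell was thinned to 2000 UMIs, and shallower cells were left out.

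The steps were tested on simulated data made from the acinar-like sums, with 50 genes at each of 4 fold sizes. The interval excluded 1 for 98% of 2-fold higher and 82% of 2-fold lower genes and for 100% of 4-fold ones, and covered the simulated ratio for 95.9% of unchanged and 93% of changed genes. A simulated list of 2-fold higher genes reached percentile 100 and a list of unchanged genes 45.3. Alternatives were other scalings (plain CPM, size factors of DESeq2 1.42.0, a total without enzymes and mitochondrial genes), other filters on cells and genes, doublets kept, other clusterings, equal weight per cell and thinning, and those added later are named in the closing section. Gene positions are from GENCODE vM21 on GRCm38.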

Results

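Caerulein, an analogue of the hormone cholecystokinin, overstimulates the enzyme-secreting acinar cells of the pancreas and causes an acute pancreatitis from which the tissue recovers within weeks. Cells of pancreata from C57BL/6J mice were profiled before treatment and 1, 7 and 28 days after it, to ask which parts of the acute response remain in the epithelium once inflammation has resolved. Fibroblast-like cells, which lay down matrix during repair, made up 21.3% of the cells of the untreated library, 58.4% of those of day 1 and 62.5% of those of day 7, while acinar-like cells made up 31.3%, 15% and 13.9%. At day 28 they made up 50.3%, and fibroblast-like cells 26.1%. Under a stricter filter on cells, acinar-like cells made up 18% untreated and 41.6% at day 28 and fibroblast-like cells 31.7% and 40.8%. The day 1 fibroblast-like share depends on where clusters are drawn, from 37.1% with coarser clusters to 72.9% with an unnamed cluster of Tnc-high and Acta2-high cells added. Each time point is 1 single-cell library of 3 mixed pancreata, so no difference between time points could be tested and the intervals cover counting error only. Cells carrying CD45 had been depleted before capture, so every share is a share of what was left after that step.

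With exact binomial intervals of 95%, the acinar-like shares were 31.3% [30.2, 32.4] in the untreated library (2128 of 6805 cells), 15% [14.3, 15.6] at day 1 (1577 of 10548), 13.9% [13.2, 14.6] at day 7 (1223 of 8801) and 50.3% [49.1, 51.4] at day 28 (3714 of 7385). Fibroblast-like cells numbered 1452, 6156, 5505 and 1929 in the same order, with shares of 21.3% [20.4, 22.3], 58.4% [57.4, 59.3], 62.5% [61.5, 63.6] and 26.1% [25.1, 27.1]. Blood endothelial-like cells, which line the vessels, made up 22.6% [21.6, 23.6] of untreated cells but 3.01% [2.70, 3.36], 2.68% [2.35, 3.04] and 1.53% [1.26, 1.84] after caerulein, and stayed low at day 28 when the acinar-like share was high. Ductal-like cells made up 11.6% [10.9, 12.4] of untreated cells and 2.60% [2.30, 2.92], 4.35% [3.94, 4.80] and 4.81% [4.33, 5.32] of the later libraries. Mesothelial-like cells, of the sheet that covers the organ, were 0.220% [0.123, 0.363] of untreated cells, 1.18% [0.979, 1.40] at day 1, 1.55% [1.30, 1.83] at day 7 and 0.162% [0.0840, 0.284] at day 28. Endocrine-like cells made up 2.94% [2.55, 3.37], 1.37% [1.16, 1.62], 3.57% [3.19, 3.98] and 3.24% [2.84, 3.67], pericytes or smooth muscle-like cells 3.94% [3.49, 4.43], 0.806% [0.644, 0.995], 1.48% [1.24, 1.75] and 2.65% [2.30, 3.05], and erythroid-like cells 2.19% [1.86, 2.57], 0.152% [0.0867, 0.246], 0.841% [0.661, 1.05] and 0.718% [0.538, 0.938]. Lymphatic endothelial-like cells (0.411% [0.274, 0.594], 0.237% [0.153, 0.350], 0.261% [0.166, 0.392] and 0.244% [0.144, 0.385]) and Schwann-like cells (0.220% [0.123, 0.363], 0.0948% [0.0455, 0.174], 0.102% [0.0468, 0.194] and 0.149% [0.0744, 0.266]) were rare throughout. The share of pericytes or smooth muscle-like cells depends on the filter on cells, with 1.73% untreated and 9% at day 1 under the stricter one. The endocrine-like share of day 1 was 0.0994% without lower-UMI copies of shared barcodes. Clusters that met no class by the naming rule held 3.22%, 17.2%, 8.73% and 10.1% of cells.

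**Figure D1:**
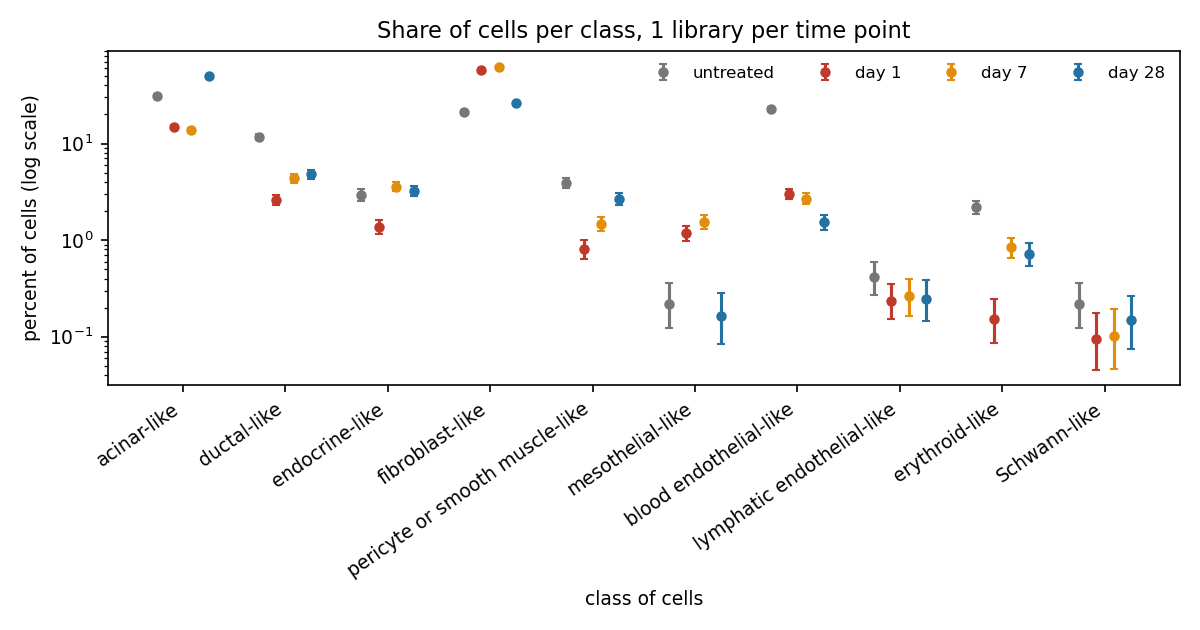
Share of cells in each class in the untreated library and 1, 7 and 28 days after caerulein, on a log scale. Bars are exact 95% binomial intervals and cover counting error only.

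Most fibroblast-like clusters came almost wholly from 1 library, and 4 of 6 acinar-like clusters mainly from 1, so a difference between time points in these classes is also a difference between clusters. Acinar-like cells of the untreated library lay mainly in cluster 8 (1639 cells), those of day 1 in cluster 14 (1426), those of day 7 in cluster 16 (862) and those of day 28 in cluster 22 (2814). Among fibroblast-like clusters, cluster 0 held 1025 untreated cells, clusters 27, 29, 33 and 34 held 1229, 1924, 1261 and 1621 day 1 cells, clusters 23, 26 and 36 held 1883, 1234 and 1944 day 7 cells, and cluster 4 held 1657 day 28 cells. Blood endothelial-like cells of all 4 libraries fell in a single cluster. Ductal-like cells lay in cluster 7 (678 untreated and 286 day 28 cells), cluster 13 (284 day 7 cells) and the shallow cluster 5 (196 day 1 cells).

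Acinar-like cells 1 day after caerulein held much less RNA of most genes of the secretory program and much more of a few injury-response genes. Digestive enzymes, the main product of these cells, had a median log2 ratio to untreated of -2.83, and genes of acinar identity -2.09. As a sum, digestive enzymes made up 69.8% of acinar-like UMIs untreated and 44.7% at day 1. The sum thus differed less than the median gene did. Keratins 8 and 18 (Krt8, Krt18) and clusterin (Clu) were 14.6-fold, 16.9-fold and 16.3-fold higher in the day 1 library. They were already seen in untreated acinar-like cells, at 163, 163 and 847 CPM. Reg3b, Reg3g, Reg2 and Reg3a, neighbouring genes for secreted lectin-like proteins of the inflamed pancreas and gut, were 78.7-fold, 66.5-fold, 28.7-fold and 31.4-fold higher. Ratios compare the summed counts of 2 single libraries after TMM scaling, which sets most genes to equal levels, so they are relative to the other genes of these cells. Fold intervals are exact, at 95%, and cover counting error only.

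Low among enzymes and their helpers at day 1 were colipase (Clps), which anchors pancreatic lipase, at 67119 CPM untreated and 2662 at day 1 (25.2-fold lower [25, 25.4]), and ribonuclease 1 (Rnase1), at 30462 and 1182 CPM (25.8-fold lower [25.5, 26.0]). The serine protease inhibitor Serpini2 was 80.6-fold lower [70.6, 92.3], the transcription factor of secretory maturity Bhlha15 (Mist1) 31.4-fold lower [22.8, 44.4], the disulfide isomerase Pdia2 22.3-fold lower [21.3, 23.4] and the methyltransferase Gnmt 23.8-fold lower [18.9, 30.3]. Also low at day 1 by the size rule were 1810028F09Rik (61.6-fold [54.2, 70.2]), the hepcidin gene Hamp2 (71.6-fold [56.8, 91.5]), the trefoil factor Tff2 (24.7-fold [24.1, 25.2]) and the intestinal pentraxin Mptx1 (0 UMIs at day 1, at least 1114-fold). Mptx1 is a gene of gut epithelium, and 97.2% of its UMIs in the untreated library lie in a cluster of 84 intestinal cells. On the high side, Reg3b stood at 113 CPM untreated and 8898 at day 1 (78.7-fold [75.0, 82.6]), Krt18 at 163 and 2758 CPM (16.9-fold [16.2, 17.6]), Clu at 847 and 13784 CPM (16.3-fold [16, 16.6]) and the phosphomannomutase Pmm1 at 9.08 and 263 CPM (29.0-fold [24.5, 34.6]). The trypsinogen genes Gm2663 and 1810009J06Rik, 135-fold [128, 142] and 62.2-fold [58.0, 66.7] higher, are described with the rest of their family.

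Of the gene lists, 23 of 31 digestive enzymes and 15 of 20 acinar identity genes were at least 2-fold lower at day 1, and both medians lay below all 10000 random lists matched on expression (percentile 0). Duct and metaplasia genes had a median of 1.57 (percentile 100; 13 of 24 at least 2-fold higher, 4 lower), with S100a11 17-fold higher [15.4, 18.8]. Genes of the gastric lineage, which appear in a stomach-like metaplasia of the injured pancreas, had a median of 2.90 over 6 genes (percentile 100), with the annexin Anxa10 50.3-fold higher [23.0, 138] and Tff2 lower as above. Inflammatory mediators and NF-kB targets stood at 0.69 (percentile 98.1; 9 of 23 higher), led by the chemokine Cxcl16 (10.4-fold [7.88, 14]) and the NF-kB subunits Relb (9.55-fold [7.01, 13.3]) and Nfkb2 (7.19-fold [5.0, 10.7]). Chaperones of the heat shock list had a median of 1.24 (percentile 98.1), with Hspb1 9.40-fold and Hspa8 9.28-fold higher, and ribosome biogenesis genes 0.94 (percentile 97.7), with Npm1 6.04-fold higher. The unfolded protein response, which adapts the endoplasmic reticulum to secretory load, was low, with a median of -0.58 (percentile 0.02, but 0.14 under plain CPM) and Sel1l 8.94-fold and Hyou1 6.74-fold lower. Amino acid transport and metabolism had a median of -0.61 (percentile 0.02), with Gatm 15.7-fold lower. Its plain CPM median was positive, at 0.11 (percentile 0). Matrix genes had a median of 1.05 (percentile 99.5), led by Timp1 (27.8-fold) and Tnc (22.4-fold), in a class where fibroblast markers made up 0.0258% of UMIs untreated and 0.0417% at day 1. RNA set free by other cells is counted in every class and was not subtracted. Cell cycle genes had medians of 0.56 for S phase (percentile 98.0) and 0.65 for G2/M (percentile 99.7). The G2/M median was 0.019 (percentile 80.0) with cells thinned to 2000 UMIs and 0.038 (percentile 72.6) in cells with at least 0.1% Malat1, so it does not stand out there. Matrix genes in the latter cells had a median of 0.48, within the middle 95% of random lists, and in all acinar-like cells 3.37 with no filter on cells and 3.34 with doublets kept. The acute phase and Reg list had a median of only 0.45 (percentile 55.1), since 6 of its 14 genes were at least 2-fold higher and 2 lower. Inside the middle 95% of the random lists, which centred above 0 at day 1 (at 0.77 for those matched to the enzymes), lay immediate early genes (-0.15, percentile 3.38, with Egr1 3.99-fold and Zfp36 3.62-fold lower), MAPK pathway output (-0.09, percentile 57.3), interferon and antigen presentation (-0.03, percentile 52.6), oxidative stress (0.75, percentile 70.3, with Srxn1 8.77-fold higher), lysosome and autophagy (0.89, percentile 88.4, with Ctsl 6.90-fold higher), oxidative phosphorylation (0.58, percentile 18.4) and endothelial activation (-1.03, percentile 7.54). Immediate early genes lay below it with cells thinned to 2000 UMIs, at -1.09 (percentile 0), and under plain CPM (percentile 1.73), but stood at 0.44 (percentile 54.6) with no filter on cells and 0.45 (percentile 58.0) with doublets kept.

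At day 7 the acinar-like cells still held less enzyme RNA than untreated cells, and the genes of cell division had their highest medians of the 3 comparisons. Digestive enzymes had a median log2 ratio of -1.54 and acinar identity genes -0.62, and the second of these 0.31 under plain CPM. As a sum, digestive enzymes made up 56.4% of acinar-like UMIs at day 7, against 69.8% untreated. The enzyme median was -0.61 under plain CPM, -0.54 with each cell weighted equally and -2.70 without cluster 16, which is near that of day 1. G2/M genes had a median of 2.53 and S phase genes 1.87, in a tissue whose acinar cells are known to divide after injury. Of the day 1 injury genes, Reg3b was still 15.7-fold higher than untreated, while Krt18 stood at 317 CPM against 163. The comparison again sets 1 library against 1 and was not tested, and most day 7 acinar-like cells lie in a cluster made mainly of day 7 cells.

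Elastase 1 (Cela1) stood at 56126 CPM untreated and 4383 at day 7 (12.8-fold [12.7, 12.9] lower) and pancreatic lipase (Pnlip) at 68958 and 6009 CPM (11.5-fold [11.4, 11.5] lower). The zymogen granule membrane protein gene Gp2 was 16.1-fold [15.7, 16.6] lower and the granule protein gene Sycn 8.93-fold lower. Also among the lowest by size were Hamp2 (92.6-fold [72.1, 121]), the cargo receptor Tmed11 (39.7-fold [32.6, 48.8]), the kallikrein Klk1b5 (20.9-fold [18, 24.3]), the immunoglobulin gene Igkc (80.9-fold [55.2, 123]) and Mptx1 (0 UMIs at day 7, at least 1227-fold). The calcium-binding protein gene S100g was 53.8-fold higher, from 1.74 to 93.4 CPM, and Reg3b stood at 1774 CPM. The other 6 of the 8 highest genes were trypsinogens.

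In the lists, 23 of 31 enzymes were at least 2-fold lower at day 7 (percentile 0) and 9 of 20 identity genes (percentile 0.08). All 22 G2/M genes and 18 of 20 S phase genes were at least 2-fold higher (both percentile 100). They were led by Mki67, a marker of cycling cells (12.3-fold [7.52, 21.8], on 16 untreated UMIs), Ube2c (8.33-fold [6.06, 11.7]), Top2a (7.86-fold [5.38, 12]) and Mcm6 (6.59-fold [4.53, 9.96]). Interferon and antigen presentation genes had their highest median here (1.27, percentile 100), with Ifi27l2a 3.22-fold and Bst2 3.10-fold higher. Gastric lineage genes stood at 3.97 over 7 genes (percentile 100). Among them the gastrokine Gkn3 was 257-fold [70.9, 2123] higher on 2 untreated UMIs, Anxa10 58.3-fold [26.7, 159] and cathepsin E (Ctse) 15.7-fold [8.69, 31.7], while Tff2 was 9.12-fold lower. Acute phase and Reg genes had a median of 1.52, percentile 100, with Reg3a 15-fold and Reg3g 10.0-fold higher. Inflammatory mediators stood at 0.90, percentile 100, with Cxcl1 2.04-fold higher. Immediate early genes (0.66, percentile 99.99), heat shock genes (0.85, percentile 99.99), ribosome biogenesis (1.13, percentile 100, with Nop56 3.90-fold higher) and the unfolded protein response (0.30, percentile 98.6, with Calr 3.33-fold higher) lay above the middle 95% of random lists. Matrix genes did too (1.29, percentile 100, with Col1a1 7.54-fold higher), where fibroblast markers made up 0.104% of UMIs against 0.0258% untreated. Ductal and metaplasia genes stood at 0.19, percentile 89.6, with Cd44 5.68-fold and Sox4 4.91-fold higher and Tm4sf1 12.7-fold lower. MAPK output (0.30, percentile 90.1), oxidative stress (-0.11, percentile 23.9, with Mt1 4.55-fold lower), lysosome and autophagy (-0.05, percentile 27.5), oxidative phosphorylation (-0.17, percentile 11.3) and amino acid metabolism (-0.20, percentile 7.39) also lay among the random lists. Immediate early genes lay within it with each cell weighted equally, at 0.18 (percentile 54.8). Endothelial activation genes were low (-1.21, percentile 0.09), but stood at 0.17 (percentile 59.0) under the stricter filter on cells, in a class where blood endothelial markers made up 0.00923% of UMIs untreated and 0.000861%, 0.000920% and 0.000425% at day 1, 7 and 28.

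At day 28 the enzyme and identity genes of acinar-like cells had medians nearer to 0 than those of the Reg genes. Digestive enzymes had a median log2 ratio of 0.26 and acinar identity genes 0.16. These depend on which cells are counted, with enzymes at -0.34 (percentile 0) at resolution 0.5 and, with cells weighted equally, enzymes at 0.75 (percentile 100.0) and identity genes at 0.62 (percentile 99.4). Acute phase and Reg genes stood at 1.18, with Reg3a 23.7-fold, Reg2 14.2-fold, Reg3g 11.5-fold and Reg3b 7.97-fold higher than untreated 28 days after the injury. The trypsin inhibitor Spink1, which guards against early activation of trypsinogen, stood at 5324 CPM untreated and 11141 at day 28 (2.09-fold [2.08, 2.11] higher). The limits are those of the other days, and plain CPM lowers every day 28 ratio by 0.53 on the log2 scale, which gives several medians near 0 the other sign.

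The 8 highest genes by size at day 28 were 6 trypsinogens, Reg2 (14.2-fold [13.5, 15]) and Reg3a (23.7-fold [17.8, 32.4]). The lowest were Mptx1, listed at 0 in this library, Igkc (12.8-fold [10.7, 15.4]), the neuropeptide galanin (Gal, 3.36-fold [3.17, 3.57]), the nuclear RNA Neat1 (3.19-fold [3.00, 3.40]), Hamp2 (2.85-fold [2.68, 3.03]), Tmed11 (1.92-fold [1.80, 2.06]), Luc7l2 (1.81-fold [1.65, 1.98]) and Snrnp70 (1.69-fold [1.53, 1.86]), the last 3 below 2-fold. Cells low in the nuclear RNA Malat1 were more frequent at day 28 than untreated, and the log2 ratio of Neat1 was -1.67 in all cells and -0.81 in those with at least 0.1% Malat1. Of the lists, 7 of 31 enzymes were at least 2-fold higher and 1 lower (percentile 15), and 1 of 20 identity genes was higher (percentile 8.74). The acute phase and Reg list lay above all random lists (6 of 12 genes higher). So did gastric lineage genes (1.70 over 6 genes, with Anxa10 26.3-fold [12, 72.3] higher), heat shock genes (0.67, with Hspa8 2.60-fold higher) and ribosome biogenesis (0.59, with Npm1 1.75-fold higher). Clu was 2.87-fold and Krt7 3.34-fold higher, but the ductal and metaplasia list had a median of -0.00, percentile 1.86, with Tm4sf1 6.94-fold lower. The unfolded protein response stood at 0.42, percentile 93.9, with Ddit3 2.64-fold and Hsp90b1 2.52-fold higher, and lysosome and autophagy at 0.41, percentile 98.0, with Ctsd 2.01-fold higher. S phase genes had a median of 0.30, percentile 99.0, G2/M genes -0.33, percentile 24.1 and inflammatory mediators -0.05, percentile 54.3. Immediate early genes (-0.34, percentile 0.01, with Egr1 1.53-fold lower), MAPK output (-0.55, percentile 1.17), interferon and antigen presentation (-0.57, percentile 0.25), oxidative stress (-0.11, percentile 1.60) and endothelial activation (-1.22, percentile 0.13) lay below the middle 95% of random lists. At resolution 0.5 the first 3 of these stood at 0.29 (percentile 98.2), 0.26 (percentile 90.3) and 0.0046 (percentile 37.4), gastric lineage genes at 0.38 (percentile 91.0), ductal and metaplasia genes at 0.34 (percentile 99.8), matrix genes at 0.56 (percentile 100.0) and oxidative phosphorylation at -0.17 (percentile 0.0400). Under the stricter filter on cells immediate early genes stood at 0.075 (percentile 2.65), interferon at 0.026 (percentile 22.1), endothelial activation at -0.50 (percentile 5.47), ductal and metaplasia genes at 0.39 (percentile 89.7) and matrix genes at 0.48 (percentile 99.1). By the main settings oxidative phosphorylation (0.16, percentile 2.83), amino acid metabolism (0.09, percentile 7.82) and matrix genes (-0.16, percentile 6.55) lay within it.

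**Figure D2:**
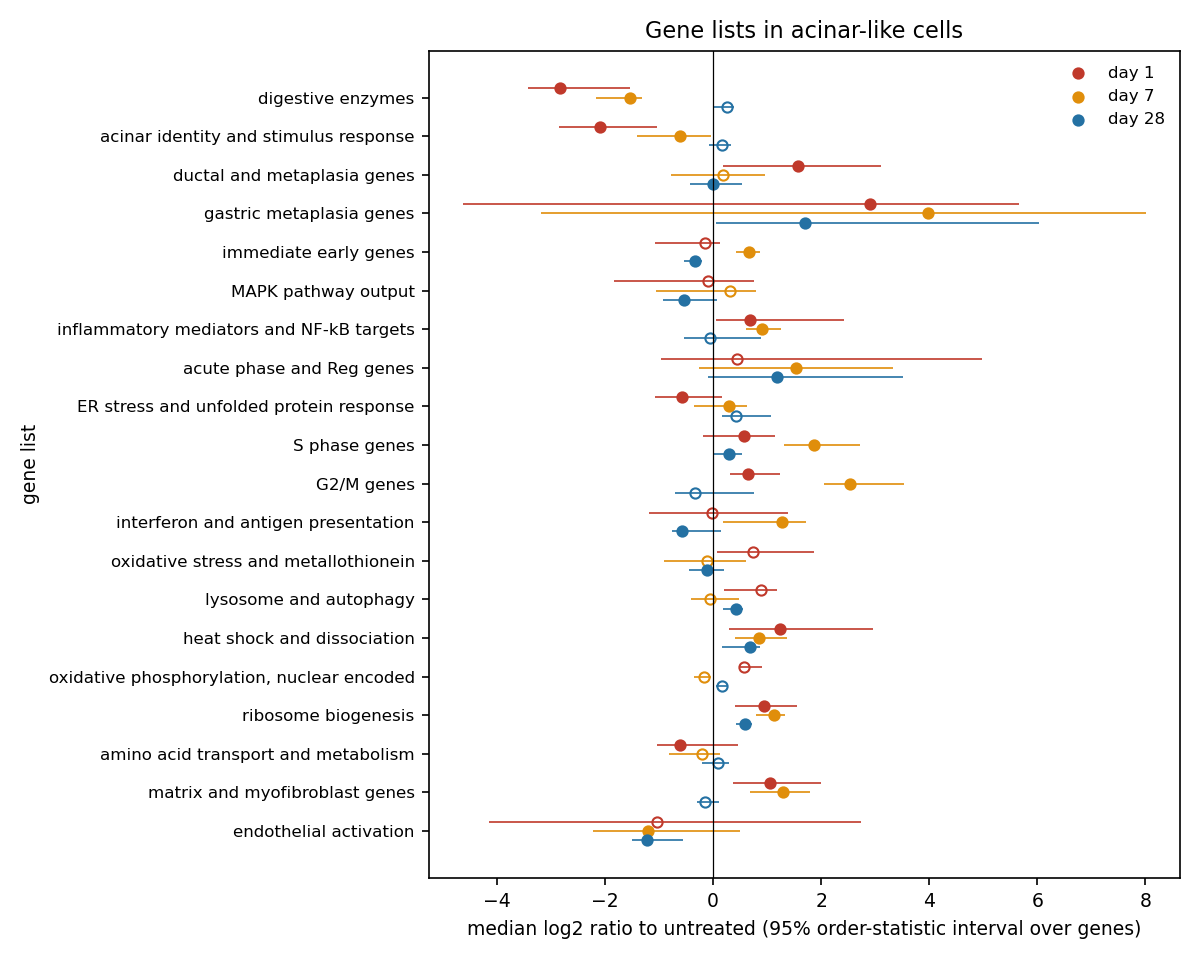
Median log2 ratio to untreated of each gene list in acinar-like cells at day 1, 7 and 28, with 95% order-statistic intervals over the genes of a list and filled points outside the middle 95% of random lists. Digestive enzymes sit at -2.83, -1.54 and 0.26, and G2/M genes at 0.65, 2.53 and -0.33.

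Trypsinogens, the inactive precursors of trypsin, are made by a family of near-identical genes on chromosome 6, and part of this family was high in acinar-like cells only in the caerulein libraries. Prss3, Gm5771, Gm10334 and Prss1 lie side by side at positions 41373814 to 41463786 (GRCm38). In the 4 libraries they made up 0.107%, 0.218%, 7.94% and 5.84% of unscaled acinar-like UMIs. 1810009J06Rik and Gm2663, at 40964754 to 40999479, made up 0.0117%, 2.07%, 1.79% and 0.571%. Because these sequences are nearly the same, the level of any single member is uncertain. At day 7 the ratios to untreated were 118-fold [112, 123] for Prss1, 81.0-fold [78.0, 84.3] for Gm5771, 37.3-fold [36.3, 38.3] for Gm10334, 15.7-fold [15.4, 16] for Prss3, 82.9-fold [78.6, 87.6] for Gm2663 and 75.4-fold [70.3, 80.9] for 1810009J06Rik. At day 28 they were 128-fold [122, 135] for Prss1, 129-fold [124, 134] for Gm5771, 100.0-fold [97.3, 103] for Gm10334, 45.7-fold [44.8, 46.6] for Prss3, 31.7-fold [30, 33.5] for Gm2663 and 134-fold [125, 144] for 1810009J06Rik. The other members made up 18.8%, 18.9%, 19.2% and 21.5% of these UMIs, and the whole family 18.9%, 21.2%, 28.9% and 27.9%. In scaled CPM Prss2 stood at 69642, 40487, 17668 and 76891 and Try5 at 40804, 71509, 49475 and 110703.

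**Figure D3:**
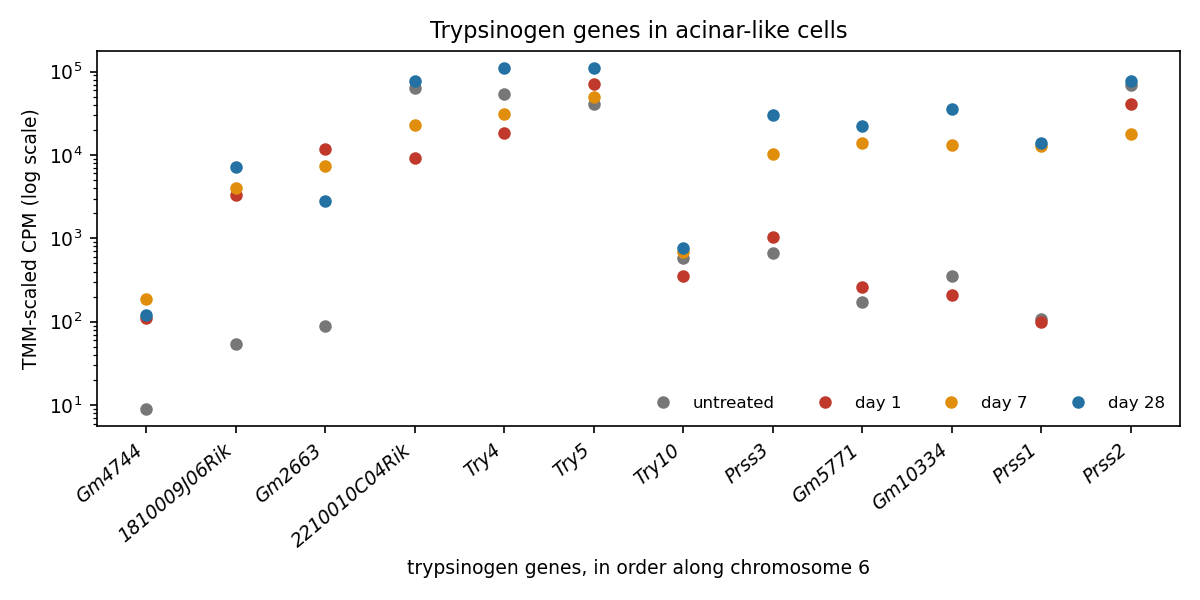
Level of each trypsinogen gene in acinar-like cells of the 4 libraries, in TMM-scaled CPM on a log axis. Prss1 sits at 108, 98.3, 12698 and 13839.9 CPM in turn.

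Of the acinar-like profile of day 1, the high genes were in part still high at day 28, and the low genes had a median near 0 that lay below all matched random lists (percentile 0). The 50 genes highest at day 1 by size, whose median log2 ratio was then 3.31, had medians of 1.17 [0.74, 1.52] at day 7 and 0.84 [0.64, 1.07] at day 28. Of these genes 46 lay above untreated at day 7 and 44 at day 28, when 18 were at least 2-fold higher, among them the trypsinogens Gm2663 and 1810009J06Rik and Reg3b, Reg3g and Reg2. The galectin Lgals3, which macrophages and injured epithelium both make, was an exception, with log2 ratios of 3.96 at day 1, -1.81 at day 7 and -2.20 at day 28. The 50 genes lowest at day 1 had a median of -3.52 then, -1.97 [-2.66, -1.51] at day 7 and 0.02 [-0.08, 0.14] at day 28. Over the alternatives the day 28 medians ranged from 0.31 to 1.04 for the high genes and from -0.57 to 0.62 for the low genes. All comparisons share the untreated library, whose counting error alone moved such medians by 0.05 in 100 simulations of unchanged libraries. Anything particular to the untreated pool would move all later ratios together and is not in that value, and no test was possible.

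**Figure D4:**
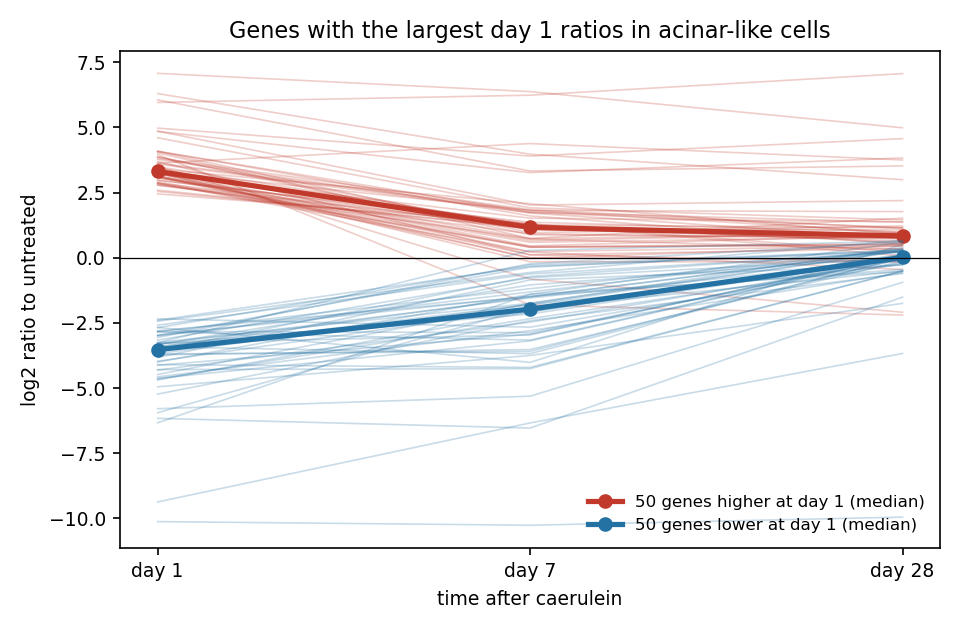
Log2 ratio to untreated of the 50 genes highest and the 50 genes lowest at day 1 in acinar-like cells, followed to day 7 and 28. The medians of the high genes are 3.31, 1.17 and 0.84, and those of the low genes -3.52, -1.97 and 0.02.

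Cycling genes differed in timing between cell classes. After thinning every cell to 2000 UMIs, G2/M UMIs were found in 14.3% [12.2, 16.6] of acinar-like cells at day 7, against 5.12% [4.13, 6.25] untreated, 6.86% [5.56, 8.34] at day 1 and 1.37% [1.02, 1.81] at day 28. The untreated and day 1 intervals overlap. In cells with at least 0.1% Malat1 the shares were 21.6% at day 7, 13.0% untreated, 12.5% at day 1 and 4.56% at day 28, and without thinning day 1 (26.8%) lay above day 7 (25.9%). In fibroblast-like cells the share was 67.4% [66.2, 68.6] at day 1, against 4.26% [3.27, 5.44] untreated, 4.15% [3.63, 4.71] at day 7 and 2.61% [1.94, 3.43] at day 28. Ductal-like cells had 35.8% [26.2, 46.3] at day 1 (34 of 95 cells deep enough) and 21.4% [16.9, 26.5] at day 7, against 4.2% [2.87, 5.91] untreated and 5.15% [3.03, 8.12] at day 28. Blood endothelial-like cells had 8.99% [7.56, 10.6] untreated, 19.4% [14.7, 24.9] at day 1, 8.57% [5.16, 13.2] at day 7 and 5.56% [2.07, 11.7] at day 28. A cell with a G2/M UMI is not shown to be dividing, since free RNA can give 1 such UMI.

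**Figure D5:**
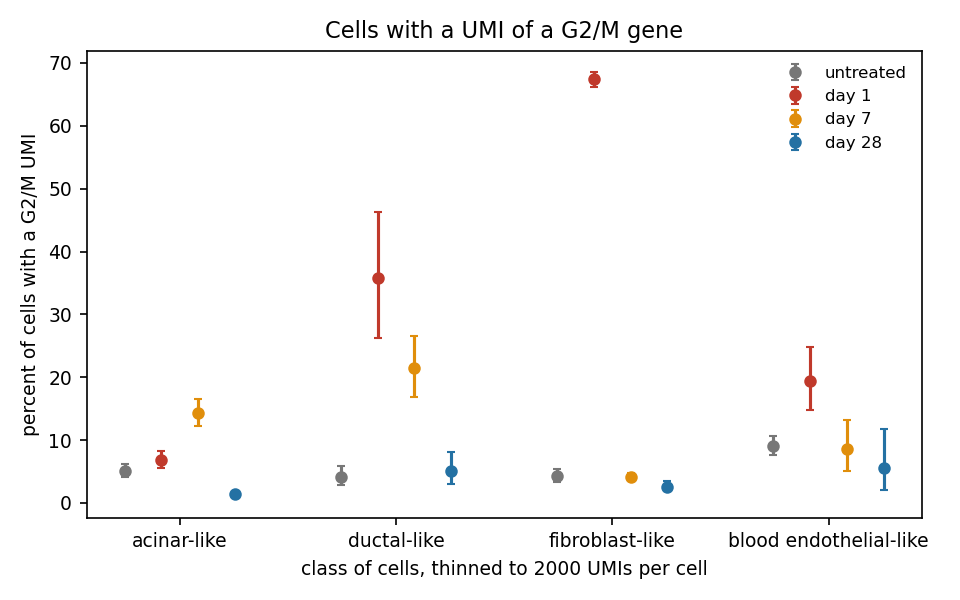
Percentage of cells with a G2/M UMI after thinning to 2000 UMIs, by class and library, with exact 95% intervals. Fibroblast-like cells peak at day 1 with 67.4% and acinar-like cells at day 7 with 14.3%.

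Fibroblast-like cells 1 day after caerulein had much more RNA of matrix, contractile and cell division genes. Timp1, an inhibitor of matrix proteases, stood at 50.3 CPM untreated and 6206 at day 1 (123-fold [115, 132] higher), the injury matrix gene tenascin C (Tnc) was 107-fold [89.9, 129] higher and the smooth muscle actin Acta2, a mark of myofibroblasts, 51.2-fold [46.7, 56.2]. G2/M genes had a median log2 ratio of 5.16 and S phase genes 3.00, with the division genes Birc5 (75.3-fold) and Pclaf (86.6-fold) among the 5 highest. Low were the stem-like fibroblast gene Clec3b (43.8-fold [42.7, 44.9]), Igfbp5 (43.9-fold), Inmt (63.0-fold), Vwa1 (49.9-fold) and Lars2 (28.5-fold). Clusters 27, 29, 33 and 34 hold nearly all of these day 1 cells, and an unnamed day 1 cluster of 1535 cells with Tnc, Timp1, Tagln and Acta2 was not counted among them.

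All 22 G2/M genes and 18 of 20 S phase genes were at least 2-fold higher in day 1 fibroblast-like cells. Matrix genes stood at 1.37, percentile 98.6, with Cthrc1 31.6-fold higher. Ribosome biogenesis (1.42, percentile 99.99, with Npm1 5.88-fold higher), the unfolded protein response (1.26, percentile 99.8, with Manf 5.35-fold higher), amino acid metabolism (0.79, percentile 97.6) and acute phase genes (1.74, percentile 100) lay above the middle 95% of random lists. Inflammatory mediators (0.85, percentile 92.3) lay within it, with the chemokines Cxcl5 197-fold [104, 431] and Ccl2 7.28-fold higher, and so did oxidative phosphorylation (1.26, percentile 97.1). Interferon and antigen presentation genes were low (-1.04, percentile 0.01, with Ifit3 4.88-fold lower), as were MAPK output (-1.16, percentile 0.02, with Spry4 11.9-fold lower), immediate early genes (-0.53, percentile 0.04) and lysosome and autophagy (-0.16, percentile 1.35). Digestive enzymes, which fibroblasts do not make, had medians of -3.72, -1.75 and 0.90 at day 1, 7 and 28, and acinar identity genes -3.77, -1.23 and 0.96.

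At day 7 fibroblast-like cells had high collagen and interferon genes and low G2/M genes. The fibrillar collagen gene Col1a1 stood at 1448 CPM untreated and 8967 at day 7 (6.19-fold higher), periostin (Postn) at 98.6 and 1271 CPM (12.9-fold [12.3, 13.5] higher), and matrix genes had a median of 1.29, percentile 100. Interferon and antigen presentation genes stood at 1.19, percentile 100, with Rsad2 6.53-fold, Ifit3 6.31-fold and Isg15 5.48-fold higher, where the same list was -1.04 at day 1. Also high by size were Thbs4 (63.4-fold [47.6, 86.3]), Wnt4 (39.0-fold), Cpz (30.2-fold) and the Wnt-binding Sfrp2 (20.3-fold), and low were Lamc3 (33.0-fold), the glucocorticoid-activating enzyme Hsd11b1 (17.9-fold), Hpgd (13.3-fold), Alkal2 (12.2-fold) and G0s2 (9.01-fold). MAPK output was -0.74, percentile 0, with the feedback inhibitors Spry4 9.02-fold and Spry1 8.51-fold lower. G2/M genes had a median of -1.75, percentile 0, though the thinned shares of untreated and day 7 cells with a G2/M UMI have overlapping intervals. Lysosome and autophagy (0.52, percentile 99.8), immediate early genes (0.53, percentile 99.6) and acute phase genes (1.94, percentile 100) were high, and S phase genes (-0.09, percentile 29.3) and inflammatory mediators (0.13, percentile 72.7) lay among the random lists. These cells lie in clusters 23, 26 and 36, which hold few cells of other libraries.

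At day 28 the matrix genes of fibroblast-like cells had higher levels than in the untreated library by their median, though not apart from random lists with doublets kept, at 0.16. The matrix list had a median of 0.53, percentile 100, with Timp1 3.67-fold and Postn 2.93-fold higher than untreated. The complement genes C7 (9.09-fold [7.83, 10.6]) and C4b (5.27-fold), the cartilage matrix gene Cilp (6.41-fold), Sult1e1 (5.12-fold) and Mfap4 (3.88-fold) were the highest by size. The lowest were Cldn15 (5.54-fold), Nmb (4.63-fold), Ogfrl1 (4.41-fold), Enpp2 (4.37-fold) and Apod (4.16-fold). G2/M genes were low (-2.07, percentile 0, with Ube2c 19.4-fold lower), though S phase genes stood at 0.07 and the thinned shares of untreated and day 28 cells with a G2/M UMI have overlapping intervals. Also, acute phase genes were high (1.54, percentile 100) and MAPK output was low (-0.37, percentile 0.01, with Spry4 3.67-fold lower). Most day 28 cells lie in cluster 4, and most untreated cells in cluster 0.

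Ductal-like cells held more lipocalin 2, Mmp7 and cell division RNA at day 1 and 7, and at day 7 genes of the gastric lineage. Lipocalin 2 (Lcn2), an iron-binding protein of inflamed epithelium, stood at 259 CPM untreated and 10466 at day 1 (40.5-fold [38.9, 42.1] higher), and was 11.4-fold higher at day 7 and 2.49-fold at day 28. The matrix protease Mmp7 was 27.1-fold [23.7, 31], 38.0-fold [33.6, 43.2] and 3.45-fold higher in turn. G2/M genes had medians of 6.05, 4.66 and 2.02, and gastric lineage genes 0.15, 6.29 and 2.92 over 5, 7 and 6 genes. Matrix genes were high in the same cells, at 5.09 and 4.11 at day 1 and 7, so RNA of their own was not separated from RNA of fibroblast-like cells. The day 28 share of cells with a G2/M UMI has an interval that overlaps the untreated one. Only 3 of the 6 gastric genes of day 28 are seen in at least 20 cells of every library, with a median of -0.08, and this filter removes genes rare in the untreated library. The day 1 class is weak, with 274 cells of median 1065 UMIs, 116 of which share their barcode with a deeper cell of another library.

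In day 1 ductal-like cells the largest ratios by size were Cxcl5 (507-fold [232, 1386]), Timp1 (329-fold [207, 557]), Cxcl14 (89.7-fold) and Col1a1 (80.5-fold [63.8, 103]), the last of these a fibroblast gene. The apolipoprotein Apoe stood at 10769.9 CPM untreated and 436 at day 1 (24.7-fold [23.2, 26.4] lower), and Ces1d (26.0-fold), Pigr (19-fold), Fmo2 (17.9-fold) and Apoc1 (17-fold) were low too. At day 7 the gastrokine Gkn3 had 0 untreated UMIs and 4788 at day 7 (at least 1861-fold higher), pepsinogen C (Pgc) was 402-fold [71.7, 15939] higher, Ctse 165-fold [45.3, 1369], Ly6d 71.0-fold, Ifi27l2a 47.0-fold [38.6, 57.9] and Ifit3 32-fold [24.6, 42.5]. Low at day 7 were Adamts16 (14.8-fold), Fmo2 (8.83-fold), Hs6st2 (7.50-fold), Lars2 (6.26-fold) and Cbs (4.73-fold). At day 28 the highest genes were Pgc, on 1 untreated UMI (2142-fold [384, 84660.5]), Pga5 (0 untreated UMIs, at least 477-fold), Obp2b (5.78-fold), Rgs5 (5.67-fold) and Meg3 (4.48-fold), with Gkn3 again from 0 UMIs (at least 82.0-fold). The lowest were Adamts9 (2.29-fold), Adamts16 (2.26-fold), Spon1 (2.21-fold), Sult1a1 (2.11-fold) and Amotl2 (2.07-fold).

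Among the lists in ductal-like cells, interferon and antigen presentation stood at 0.34, 2.86 and 0.43 at day 1, 7 and 28, with 17 of 21 genes at least 2-fold higher at day 7 and Isg15 17.5-fold higher. S phase genes had medians of 2.99, 1.72 and 0.05, acute phase and Reg genes 1.17, 2.75 and 1.64, inflammatory mediators 1.35, 0.83 and 0.23, and ductal and metaplasia genes 1.35, 0.37 and 0.08. Immediate early genes stood at -1.19, -0.43 and -0.04, MAPK output at -0.94, -0.32 and 0.21, and endothelial activation at 2.77, 1.01 and 0.81, the last of these -0.44 with doublets kept. Matrix genes had medians of 5.09, 4.11 and 1.45 in a class that is not their main source.

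Blood endothelial-like cells had higher endothelial activation genes after caerulein. Their list stood at 1.02, 1.16 and 1.44 at day 1, 7 and 28, above all random lists each time. The venular chemokine receptor Ackr1 was 6.11-fold higher at day 1 and 12.3-fold [10.1, 14.9] at day 28, and P-selectin (Selp), which slows rolling leukocytes, 4.88-fold and 6.60-fold. The angiogenic glycoprotein Lrg1 stood at 109 CPM untreated and 1949 at day 1 (17.9-fold [16.6, 19.3] higher) and was 6.29-fold higher at day 28. The day 28 class has few cells, its share having gone from 22.6% of untreated cells to 1.53%. A different mix of vessel types, or RNA of other cells, was not separated from a change within cells.

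At day 1 the T cell chemokine gene Cxcl9 was 169-fold higher in blood endothelial-like cells, Fjx1 65.3-fold and Scgb3a1 22.5-fold. At day 7 the matrix genes Cilp (166-fold [86.6, 367]) and Mfap4 (122-fold [54.9, 337]) led, and Gpx3 (26.0-fold) and Serping1 (25.4-fold) were also high. At day 28 the highest were the trypsinogens 1810009J06Rik (1326-fold [450.5, 6459], on 3 untreated UMIs), Prss1 (484-fold), Gm10334 (257-fold) and Gm5771 (255-fold), all acinar genes, and Ccl21a (269-fold). The capillary gene Rbp7 was 7.64-fold lower at day 1 and 9.03-fold at day 7, and the capillary genes Car4 and Gpihbp1 were 4.48-fold and 3.52-fold lower at day 28. Cytl1 and Cyp1a1 were listed at 0 in all caerulein libraries and Glycam1 at day 1 and 7, and Mptx1 had 0 UMIs at day 1 (at least 29.3-fold) and day 7 (at least 36.7-fold) and was listed at 0 at day 28. Interferon genes had medians of -0.73, 0.24 and -0.65, inflammatory mediators 0.75, 0.80 and 0.44, G2/M genes 0.81, -1.38 and 0.60, and matrix genes 3.13, 2.36 and 0.98, the last of these -0.026 with doublets kept.

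Endocrine-like cells, rich in islet hormone RNA, were compared at day 7 and 28. The stress-responsive signalling gene Rgs2 was 4.07-fold [3.50, 4.74] higher at day 7 and 3.83-fold at day 28. Somatostatin (Sst) was 3.06-fold lower at day 7, and ghrelin (Ghrl) stood at 6.77 CPM untreated and 1133 at day 28 (167-fold [125, 229] higher). A hormone gene moves with the share of its islet or gut cell type, which was not separated. Day 1 was left out, as 135 of its 145 cells share a barcode with a deeper cell of another library.

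Also high in day 7 endocrine-like cells were the feedback inhibitor Errfi1 (3.18-fold), Pdyn (3.18-fold), Trib1 (2.99-fold) and Cebpd (2.71-fold), and low were Reg4 (0 UMIs at day 7, at least 398-fold, a gene with 89.4% of its untreated UMIs in a cluster of 84 intestinal cells), Tmsb15b2 (2.99-fold) and Rbp4 (2.24-fold). At day 28 Dusp5 (4.15-fold), the NF-kB inhibitor Nfkbia (3.95-fold) and Gadd45b (3.65-fold) were high, while Pyy (1.66-fold), Rbm3 (1.51-fold) and Ttr (1.5-fold), the lowest by size, stayed below 2-fold. Insl5 was listed at 0 at both times and Reg4 at day 28. Immediate early genes had medians of 0.69 and 0.32 at day 7 and 28, inflammatory mediators 1.10 and -0.06, acute phase and Reg genes 3.52 and 1.13, amino acid metabolism -0.34 and -0.26, and G2/M genes -2.50 and -2.57.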

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

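The tests of mixed pancreata and of shallow sequencing were written before their results had been seen. Those of read division, swapped and released RNA for the trypsinogens, of free RNA in droplets and of shared barcodes were written after, and some of them replace earlier tests. None of the differences between classes named here was tested, since each time point is 1 library.

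At day 7 G2/M genes stood apart between classes, with a median of 2.53 in acinar-like cells against -1.75 in fibroblast-like cells (a difference of 4.28), -1.38 in blood endothelial-like cells (3.91) and -2.50 in endocrine-like cells (5.03). Endothelial activation genes were high in blood endothelial-like cells and low in acinar-like cells, at 1.16 against -1.21 at day 7 (a difference of -2.37) and 1.44 against -1.22 at day 28 (-2.65). In ductal-like cells they stood at 1.01 at day 7, a difference of -2.22. The acinar-like median of day 7 was 0.17, at percentile 59.0, under the stricter filter on cells, and that of day 28 -0.50, at percentile 5.47, so the contrast with acinar-like cells depends on the filter. In the untreated acinar-like class 0.00923% of UMIs are of blood endothelial markers, more than in any later library, and the differences were not tested.

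Clusters without a name held signal that no comparison used. Cluster 30 held 14.6% of day 1 cells (1535) and 0 untreated cells, and its leading genes were Tnc, Timp1, Tagln and Acta2, markers of both fibroblasts and smooth muscle. Cluster 18 held 6.44% of day 7 cells (567) against 0.382% of untreated cells, had a median of 761.5 UMIs and was led by Lars2, Gm42418 and trypsinogens. Cluster 32 held 7.98% of day 28 cells (589) against 0.0147% of untreated cells and was led by Lars2, Gm10334 and mitochondrial genes.

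The first pattern weighed is the block of trypsinogen genes Prss3, Gm5771, Gm10334 and Prss1, at 0.567% of the family's UMIs in untreated acinar-like cells and 27.5% and 20.9% at day 7 and 28. Reads moved within the family would keep its share, but this was at least 1.48 times the untreated share each time. A change in reads left uncounted was not tested. Swapping from other libraries is argued against as the whole cause, since a source would need more block UMIs and as high a share of the family. Day 7 had 2041134 block UMIs in all cells, 28.0% of the family, and day 28 3084784, 20.9%, so each falls short as source of the other, at best by a ratio of 0.745 [0.702, 0.794], and the untreated and day 1 libraries had 21654 and 58962. RNA released by other kinds of cell would need a source richer in the block than acinar-like cells. At day 7 this is argued against, since the highest ratio of a cluster of other cells to acinar-like cells was 0.586 [0.447, 0.890]. At day 28 the highest ratio was 0.5855, and release cannot be told apart only because the interval for 17 cells of cluster 6 reaches 1.07. In day 28 cells the block's share in shallower cells was 0.773 of that in deeper ones, where released RNA would make it higher. Mixed pancreata with and without the block remain a possible explanation, since 26.8% of day 28 cells lay at or below 7.85% of family UMIs, the upper end of untreated cells. At day 7 it was 8.997%, between the bounds set for and against this cause, but 21.1% of cells with at least 0.1% Malat1, against 21.8% at day 28. Few cells had a share as low as the untreated median of 0.205%, since the lowest 2.5% of cells end at 1.34% at day 7 and 1.48% at day 28. Genotyping the mice for the block would test it. Time after caerulein stays open and was not tested. Replicate mice per time point would test it.

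The second pattern is the low nuclear RNA of many acinar-like droplets, with 73.4%, 88.0%, 70.9% and 91.8% of them in the 4 libraries under 0.1% Malat1. Free RNA alone cannot be told apart. Per UMI of Col1a1, Col1a2 and Col3a1, these droplets had at least 18.6 times the enzyme UMIs of any other class in their library. Those classes can hold collagen RNA of their own. Shallow sequencing is argued against, since at the ductal-like share at least 99.9977% of the droplets would show a Malat1 UMI. Damaged cells that kept cytoplasm may explain it, which was not tested and which staining for intact nuclei would test. No biological explanation was tested.

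The third pattern is 927 of 32324 barcodes that occur in more than 1 library. Chance sharing by separate cells is argued against, since 74.8% of lower-UMI copies lay in the class of their highest copy, against at most 28.8% in 1000 shuffles. Reads swapped between libraries of the lane remain possible, since copies shared the class of their highest copy 2.95 times as often as after shuffling, just short of the 3 times set for this explanation, so the test does not decide. Libraries with unique dual indexes would test it.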

How the results depend on the processing

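Of the alternatives, those added after the data were seen are the removal of lower copies of shared barcodes, the Malat1 minimum, cluster 30 as fibroblast-like, the removal of cluster 16 and both treatments of genes removed before deposit, and the others were planned. The low enzyme medians of acinar-like cells at day 1 and day 7, the high G2/M and S phase medians at day 7 and the high acute phase and Reg median at day 28 kept their sign under all alternatives run. Medians near 0 at day 28 did not, and the ductal and metaplasia list, at -0.00, took a positive sign under 9 of them. Under plain CPM every acinar-like log2 ratio is higher by 0.72 at day 1 and 0.93 at day 7 and lower by 0.53 at day 28, and under a total without enzymes and mitochondrial genes the shifts are -0.29, 0.30 and -0.49. In fibroblast-like cells these shifts are -0.41, -0.15 and -0.21 under plain CPM and -0.48, -0.20 and -0.18 under the other total. No named gene of acinar-like cells changed sign, while 451, 524 and 419 of their values at day 1, 7 and 28 moved past their counting intervals and 401, 581 and 433 did not. Counting genes removed before deposit as 0 moved no value. No paired analysis was possible because each time point is 1 library. In classes not followed by setting, pericytes or smooth muscle-like cells made up 1.73% untreated and 9% at day 1 under the stricter filter on cells, and 1.84% untreated with doublets kept. Under the stricter filter endocrine-like cells made up 3.63%, 0.175%, 3.14% and 4.93% in the order of the libraries. Erythroid-like cells then made up 1.41%, 0.0617%, 0.270% and 0.195%. No cluster was named Schwann-like at resolution 0.5. For gene lists, the followed genes, G2/M shares and the shares of acinar-like, ductal-like, fibroblast-like and blood endothelial-like cells, values that left the 95% interval of the reported value, or changed sign, follow by setting.

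With plain CPM, the medians in acinar-like cells at day 1 were 0.57 for immediate early genes (sign changed from -0.15), 0.14 for unfolded protein response (sign changed from -0.58), 1.28 for S phase, 1.36 for G2/M, 1.61 for lysosome, 1.30 for oxidative phosphorylation, 1.66 for ribosome biogenesis and 0.11 for amino acid metabolism (sign changed from -0.61). Medians of -0.61 for digestive enzymes, 0.31 for acinar identity (sign changed from -0.62), 1.12 for ductal and metaplasia genes, 1.60 for immediate early genes, 1.24 for MAPK output, 1.84 for inflammatory mediators, 1.23 for unfolded protein response and 2.80 for S phase were found in acinar-like cells at day 7. Medians of 2.20 for interferon, 0.82 for oxidative stress (sign changed from -0.11), 0.88 for lysosome (sign changed from -0.05), 1.78 for heat shock, 0.76 for oxidative phosphorylation (sign changed from -0.17), 2.06 for ribosome biogenesis, 0.73 for amino acid metabolism (sign changed from -0.20) and 2.22 for matrix genes were found in acinar-like cells at day 7. Medians of -0.26 for digestive enzymes (sign changed from 0.26), -0.37 for acinar identity (sign changed from 0.16), -0.53 for ductal and metaplasia genes, -0.87 for immediate early genes, -1.08 for MAPK output and -0.58 for inflammatory mediators were found in acinar-like cells at day 28. Medians of -0.11 for unfolded protein response (sign changed from 0.42), -0.23 for S phase (sign changed from 0.30), -0.86 for G2/M, -1.10 for interferon, -0.64 for oxidative stress and -0.11 for lysosome (sign changed from 0.41) were found in acinar-like cells at day 28. Medians of 0.15 for heat shock, -0.36 for oxidative phosphorylation (sign changed from 0.16), 0.067 for ribosome biogenesis, -0.43 for amino acid metabolism (sign changed from 0.09), -0.68 for matrix genes and -1.75 for endothelial activation were found in acinar-like cells at day 28. A median of 0.20 for ribosome biogenesis was found in blood endothelial-like cells at day 7. A median of 1.00 for ribosome biogenesis was found in ductal-like cells at day 1. Medians of 0.96 for immediate early genes, 0.66 for unfolded protein response, 0.26 for oxidative stress (sign changed from -0.01), 0.38 for lysosome and 0.18 for oxidative phosphorylation (sign changed from -0.09) were found in endocrine-like cells at day 7. Medians of 0.85 for oxidative phosphorylation and 1.01 for ribosome biogenesis were found in fibroblast-like cells at day 1. A median of -0.27 for oxidative stress was found in fibroblast-like cells at day 7. Medians of 0.70 for digestive enzymes, -0.094 for inflammatory mediators (sign changed from 0.11), 0.013 for unfolded protein response, -0.14 for S phase (sign changed from 0.07), -0.084 for oxidative stress (sign changed from 0.12), -0.024 for lysosome (sign changed from 0.18), -0.10 for oxidative phosphorylation (sign changed from 0.10) and -0.050 for ribosome biogenesis (sign changed from 0.16) were found in fibroblast-like cells at day 28. Medians of 2.11 for the day 1 high genes at day 7, 0.31 for the day 1 high genes at day 28, -0.93 for the day 1 low genes at day 7 and -0.49 for the day 1 low genes at day 28 (sign changed from 0.02) were found. With CPM over a total without enzymes and mitochondrial genes, the median in acinar-like cells at day 1 was 0.29 for oxidative phosphorylation. Medians of -1.24 for digestive enzymes, 0.96 for immediate early genes, 0.13 for oxidative phosphorylation (sign changed from -0.17) and 1.43 for ribosome biogenesis were found in acinar-like cells at day 7. Medians of -0.22 for digestive enzymes (sign changed from 0.26), -0.33 for acinar identity (sign changed from 0.16), -0.49 for ductal and metaplasia genes, -0.83 for immediate early genes, -1.03 for MAPK output, -0.066 for unfolded protein response (sign changed from 0.42), -0.19 for S phase (sign changed from 0.30) and -0.82 for G2/M were found in acinar-like cells at day 28. Medians of -1.05 for interferon, -0.60 for oxidative stress, -0.073 for lysosome (sign changed from 0.41), -0.32 for oxidative phosphorylation (sign changed from 0.16), 0.11 for ribosome biogenesis, -0.39 for amino acid metabolism (sign changed from 0.09), -0.64 for matrix genes and -1.71 for endothelial activation were found in acinar-like cells at day 28. A median of 0.91 for ribosome biogenesis was found in ductal-like cells at day 1. Medians of 0.65 for unfolded protein response, 0.25 for oxidative stress (sign changed from -0.01), 0.37 for lysosome and 0.18 for oxidative phosphorylation (sign changed from -0.09) were found in endocrine-like cells at day 7. Medians of -4.24 for acinar identity, 4.68 for G2/M, 0.78 for oxidative phosphorylation, 0.94 for ribosome biogenesis and 0.89 for matrix genes were found in fibroblast-like cells at day 1. Medians of -1.43 for acinar identity, -0.073 for inflammatory mediators (sign changed from 0.13), -0.32 for oxidative stress, 0.12 for heat shock and -0.22 for oxidative phosphorylation were found in fibroblast-like cells at day 7. Medians of 0.72 for digestive enzymes, -0.069 for inflammatory mediators (sign changed from 0.11), 0.038 for unfolded protein response, -0.12 for S phase (sign changed from 0.07), -0.059 for oxidative stress (sign changed from 0.12), 0.00066 for lysosome, -0.080 for oxidative phosphorylation (sign changed from 0.10) and -0.025 for ribosome biogenesis (sign changed from 0.16) were found in fibroblast-like cells at day 28. Medians of 1.63 for the day 1 high genes at day 7, 0.49 for the day 1 high genes at day 28 and -0.57 for the day 1 low genes at day 28 (sign changed from 0.02) were found. With median-of-ratios size factors, the median in acinar-like cells at day 28 was 0.038 for ductal and metaplasia genes (sign changed from -0.00). The scaling settings shift every gene of a comparison by 1 constant, which is the cause of these shifts.

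With no minimum of UMIs, the median in acinar-like cells at day 28 was 0.040 for ductal and metaplasia genes (sign changed from -0.00). A median of -0.0077 for the day 1 low genes at day 28 (sign changed from 0.02) was found. With no filter on cells, the medians in acinar-like cells at day 1 were 0.44 for immediate early genes (sign changed from -0.15), 0.38 for oxidative phosphorylation and 3.37 for matrix genes. Of cells, 53.6% were fibroblast-like at day 1. With the stricter filter on cells, the medians in acinar-like cells at day 7 were 0.87 for immediate early genes, 1.48 for inflammatory mediators, -0.41 for oxidative phosphorylation, 2.07 for matrix genes and 0.17 for endothelial activation (sign changed from -1.21). Medians of 0.39 for ductal and metaplasia genes (sign changed from -0.00), 0.075 for immediate early genes (sign changed from -0.34), 0.026 for interferon (sign changed from -0.57), 0.48 for matrix genes (sign changed from -0.16) and -0.50 for endothelial activation were found in acinar-like cells at day 28. A median of -5.09 for digestive enzymes was found in ductal-like cells at day 1. Medians of -5.35 for digestive enzymes, -5.06 for acinar identity and 5.47 for G2/M were found in fibroblast-like cells at day 1. A median of -0.047 for the day 1 low genes at day 28 (sign changed from 0.02) was found. Of cells, 18% were acinar-like untreated, 13.2% acinar-like at day 1, 11.4% acinar-like at day 7, 41.6% acinar-like at day 28, 13.1% ductal-like untreated, 1.48% ductal-like at day 1 and 3.72% ductal-like at day 7. Of cells, 6.49% were ductal-like at day 28, 31.7% fibroblast-like untreated, 39.1% fibroblast-like at day 1, 74.2% fibroblast-like at day 7, 40.8% fibroblast-like at day 28, 27.7% blood endothelial-like untreated and 2.32% blood endothelial-like at day 28. Of acinar-like cells, 18.9% at day 7 had a G2/M UMI. With doublets kept, the medians in acinar-like cells at day 1 were 0.45 for immediate early genes (sign changed from -0.15), 0.39 for oxidative phosphorylation and 3.34 for matrix genes. In acinar-like cells, matrix genes had a median of 1.90 at day 7. Ductal and metaplasia genes there had 0.030 (sign changed from -0.00) at day 28. Medians of 0.62 for digestive enzymes and -0.026 for matrix genes (sign changed from 0.98) were found in blood endothelial-like cells at day 28. A median of -2.67 for digestive enzymes was found in ductal-like cells at day 7. Medians of -0.30 for digestive enzymes (sign changed from 0.08) and -0.44 for endothelial activation (sign changed from 0.81) were found in ductal-like cells at day 28. Of cells, 15.4% were acinar-like at day 7, 23.3% fibroblast-like untreated and 49.5% fibroblast-like at day 1. Doublets had been removed from the untreated library only. The cause was not tested for these settings.

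With clusters at resolution 0.5, the median in acinar-like cells at day 1 was 0.25 for oxidative phosphorylation. A median of -0.54 for oxidative phosphorylation was found in acinar-like cells at day 7. Medians of -0.34 for digestive enzymes (sign changed from 0.26), 0.34 for ductal and metaplasia genes (sign changed from -0.00), 0.29 for immediate early genes (sign changed from -0.34), 0.26 for MAPK output (sign changed from -0.55), 0.0046 for interferon (sign changed from -0.57), -0.17 for oxidative phosphorylation (sign changed from 0.16), 0.56 for matrix genes (sign changed from -0.16) and -0.44 for endothelial activation were found in acinar-like cells at day 28. Medians of 0.64 for the day 1 high genes at day 28 and -0.37 for the day 1 low genes at day 28 (sign changed from 0.02) were found. Of cells, 27.1% were acinar-like untreated, 58.1% acinar-like at day 28 and 37.1% fibroblast-like at day 1. Of acinar-like cells, 3.46% untreated had a G2/M UMI. With clusters at resolution 2, the medians in acinar-like cells at day 7 were 0.86 for immediate early genes and 1.92 for matrix genes. A median of 0.0032 for ductal and metaplasia genes (sign changed from -0.00) was found in acinar-like cells at day 28. Of cells, 15.3% were acinar-like at day 7 and 61.9% fibroblast-like at day 1. With variable genes chosen without enzymes, the median in acinar-like cells at day 28 was 0.072 for ductal and metaplasia genes (sign changed from -0.00). Of cells, 49.8% were fibroblast-like at day 1. As to why class edges move with the clustering, the cause was not tested.

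With each cell weighted equally, the medians in acinar-like cells at day 7 were -0.54 for digestive enzymes, 0.18 for immediate early genes, 1.90 for G2/M and 0.18 for oxidative phosphorylation (sign changed from -0.17). Medians of 0.75 for digestive enzymes, 0.62 for acinar identity, -0.43 for ductal and metaplasia genes, -0.55 for inflammatory mediators, -0.88 for G2/M, 0.35 for amino acid metabolism and -0.38 for matrix genes were found in acinar-like cells at day 28. Medians of 0.39 for the day 1 high genes at day 28, -0.85 for the day 1 low genes at day 7 and 0.62 for the day 1 low genes at day 28 were found. With cells thinned to 2000 UMIs, the medians in acinar-like cells at day 1 were -1.09 for immediate early genes and 0.019 for G2/M. Medians of -0.83 for digestive enzymes, 0.24 for immediate early genes, 0.65 for unfolded protein response and 0.058 for oxidative phosphorylation (sign changed from -0.17) were found in acinar-like cells at day 7. Medians of 0.60 for digestive enzymes, 0.48 for acinar identity, -0.57 for immediate early genes, -0.73 for G2/M and -0.23 for endothelial activation were found in acinar-like cells at day 28. Medians of 0.58 for the day 1 high genes at day 28, -1.16 for the day 1 low genes at day 7 and 0.37 for the day 1 low genes at day 28 were found. With cells thinned to 1000 UMIs, the shares of acinar-like cells with a G2/M UMI were 2.93% for untreated, 4.21% for day 1, 9.47% for day 7 and 0.835% for day 28. With no thinning, the shares of acinar-like cells with a G2/M UMI were 10.5% for untreated, 26.8% for day 1, 25.9% for day 7 and 3.63% for day 28. Weights and depth changed which cells count most, and the cause was not tested.

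With only cells with at least 0.1% of UMIs from Malat1, the medians in acinar-like cells at day 1 were -3.53 for digestive enzymes and 0.038 for G2/M. Medians of -1.26 for digestive enzymes, 0.30 for immediate early genes and 0.31 for oxidative phosphorylation (sign changed from -0.17) were found in acinar-like cells at day 7. Medians of 0.25 for ductal and metaplasia genes (sign changed from -0.00), 0.11 for immediate early genes (sign changed from -0.34), 0.16 for lysosome, 0.15 for matrix genes (sign changed from -0.16) and -1.64 for endothelial activation were found in acinar-like cells at day 28. Medians of 1.52 for the day 1 high genes at day 7 and -0.34 for the day 1 low genes at day 28 (sign changed from 0.02) were found. Of acinar-like cells, 13.0% untreated, 12.5% at day 1, 21.6% at day 7 and 4.56% at day 28 had a G2/M UMI. With only genes seen in 20 cells of every library, the median in ductal-like cells at day 28 was -0.083 for gastric lineage (sign changed from 2.92). With cluster 30 in the fibroblast-like class, the share of cells was 72.9% for fibroblast-like at day 1. With cluster 16 left out, the medians in acinar-like cells at day 7 were -2.70 for digestive enzymes and -0.41 for oxidative phosphorylation. With lower copies of shared barcodes left out, the median in acinar-like cells at day 28 was 0.068 for ductal and metaplasia genes (sign changed from -0.00). Of cells, 14.1% were acinar-like at day 1, 1.57% ductal-like at day 1, 3.89% ductal-like at day 7, 61.1% fibroblast-like at day 1 and 65.8% fibroblast-like at day 7. For these later alternatives too, the cause was not tested.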

Other observations

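All of these points were noticed after the data had been seen, and none was tested. The untreated library holds a cluster of 84 intestinal cells, 1.23% of its cells, and no other library has cells in that cluster, with 88.8% to 97.2% of the untreated UMIs of genes such as Muc2, Tff3, Clca1 and Mptx1. Cluster 19, a shallow unnamed cluster led by Mptx1 and Agr2, had 38, 45, 45 and 17 cells in the order of the libraries, and 60% of its cells were lower-UMI copies of shared barcodes. Intestinal genes thus had UMIs in other libraries too, with Mptx1 at 117048 untreated, 1244 at day 1 and 1243 at day 7. Agr2 was less uneven, at 18386 untreated and 1957 at day 7. Lower-UMI copies had a median of 1.15% of the UMIs of their highest copy. Reads swapped from the untreated library could give such counts of Mptx1, so intestinal cells in the caerulein libraries are not shown. A smooth muscle-like cluster led by Actg2 had 144 untreated cells and 4, 7 and 38 in the later libraries.

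The immunoglobulin gene Igkc had 78733 UMIs in the untreated library, 9168 at day 7 and 16745 at day 28, and was listed at 0 at day 1. Igha had 15791 untreated UMIs and was listed at 0 in all caerulein libraries. A gene listed at 0 may have been removed before deposit, so its level there is not known. The hormone gene Insl5 was listed at 0 in them, with 6783 of 6883 untreated UMIs in endocrine-like cells.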
